A study of Mus musculus with 2 samples.

How the data were processed

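The series holds 2 libraries from MIN6 cells: anti-CtBP2 ChIP replicate 1 and input replicate 1. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, CtBP2 was precipitated with an antibody, and libraries were made with a commercial DNA library kit. A control IgG precipitation, which the labels' protocols also name, was not analysed here. The deposited files hold aligned reads, 1 line per read with its chromosome, start, end and strand, and no peaks. The positions are genome coordinates of the other kind of unit, in bp. The name column, taken as a count, is 1 on every deposited line, so that the sum over lines is a raw read count with no normalization. The score column is 0 on every deposited line, so no mapping quality is given. The submitters' processing notes name BWA without a version, SAMtools 0.1.19, bedtools 2.17.0 and the build mm9, without settings or order. Whether reads were filtered by mapping quality or how reads with several matches were placed is not given in the sources used here. Repeated reads at the same position were present in the deposited files.

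The reads were 36 bp long and 49.9% of them lay on the minus strand in each library. Reads on the 21 main nuclear chromosomes were used, and 1 read per position and strand was kept in each library. The mitochondrial chromosome held 0.00702% of ChIP and 0.294% of input reads and was left out of the region calls. Strand cross-correlation, searched from 80 to 400 bp in steps of 5 bp, gave a fragment length of 220 bp in ChIP and 205 bp in input, and 5 prime ends of both libraries were moved toward the fragment centre by 0.5 of the ChIP value.

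Regions were called with scripts written in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. Windows of 200 bp in steps of 50 bp were tested with a Poisson test of the ChIP count against the largest of the genome mean and the scaled input over 1, 5 and 10 kb. Input was scaled by the ratio of total reads, and p-values were adjusted with the Benjamini-Hochberg method over 26834367 windows that held at least 1 read in either library. Windows with an adjusted p of at most 0.01 and at least 3 times the expected count were joined when within 200 bp. Windows with input of at least 10 times the genome mean, a limit of 9.66 reads, were left out, which removed 184184 windows. The thresholds, the exclusion, the exchanged call, the random split of the ChIP reads into 2 parts and the rule for named regions were set before the data were examined. That rule takes the 12 regions with the highest fold over the local expected count among those with an adjusted p of at most 1e-05, outside high-input windows and on autosomes or X. The fixed plan also held promoter, gene list, neighbouring gene and motif results for use with an annotation and sequence of the build of the files. None was used here, no coordinates were converted between builds, and these results were not run.

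The call was tested on simulated data with 400 planted sites on a chromosome with the mean depth of these libraries, reads in regions included. It was run without the high-input exclusion, over 826283 windows. With flat input, 0 of 50 sites at 5-fold, 21 of 50 at 10-fold, 45 of 50 at 20-fold and 50 of 50 at 40-fold were found. With input raised at the site the numbers were 0, 2, 44 and 50 of 50. A window near the genome mean of these libraries therefore needed a fold well above 5 to be found. Away from the planted sites, 3 regions were called, a number that does not carry over to these libraries. Simulated reads were independent, and both simulated libraries followed 1 depth profile of 10 kb bins. Simulated ChIP background was also above the 1.189 reads per kb found outside regions called without the exclusion.

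Blocks of extreme depth were 10 kb bins with at least 100 times the median of 42 input reads, counted with all deposited reads, and joined when adjacent. Background bins were 10 kb bins with input reads and a ChIP count at or below the median of such bins. Choosing them by ChIP count lowers their ChIP to input ratio. Background depth per chromosome left out blocks of extreme depth and regions with 2 kb on each side. Regions were shuffled within chromosomes over bins that held input reads. Intervals on read counts are 95% Poisson intervals and those on shares are 95% Wilson intervals. They cover counting error only, since reads from amplified libraries without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9.

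Other settings fixed in advance for the region count were all deposited reads, background-bin scaling, a stricter adjusted p of 1e-05, a fold of at least 5, local input over 10 kb only, windows of 500 bp, a fixed shift of 100 bp, no high-input exclusion and the parts of the ChIP reads. For the share of reads, all deposited reads, the stricter adjusted p and the fixed shift were fixed in advance, and the other settings were added after the values were seen. Also added then were the exclusion and scaling changed together, input thinned to the ChIP read number, the exchanged call with background-bin scaling, and the description of the full set. The 2 density groups, the input-only call, the blocks of extreme depth and the chromosome X comparison were also added then.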

Results

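CtBP2 occupancy was studied in MIN6 cells, a mouse insulinoma line widely used as a model of pancreatic beta cells, kept under regular culture conditions. CtBP2 is a transcriptional co-repressor that binds NAD(H) and reaches DNA through partner proteins, so the question of the experiment was which parts of the beta cell genome it occupies. The data were 1 chromatin immunoprecipitation (ChIP) library made with an antibody against CtBP2 and 1 input library of sheared chromatin made without immunoprecipitation. The ChIP library held 34890624 aligned reads of 36 bp and the input library 20896067. After 1 read per chromosome, position and strand was kept, 8474671 ChIP reads (24.3% of nuclear reads, 4.12 reads per position) and 12471942 input reads (59.9%, 1.67 reads per position) remained. With 1 library per group there was no replicate check, and every test below compared the reads of these 2 libraries, not conditions. CtBP2 regions are places where reads of the ChIP library exceeded the expected count. No IgG library and no library from cells without CtBP2 was analysed, so precipitation of DNA not occupied by CtBP2 stays open. All positions are given 1-based on mouse build mm9. No gene annotation or sequence of that build was used here, so regions are named by position and not by gene.

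CtBP2 regions were mostly short and lay on every nuclear chromosome. The count with windows of very high input left out, the setting fixed in advance, was 21782 regions covering 8.601 Mb, or 0.3331% of the 2582 Mb analysed. These regions had a median width of 300 bp (interquartile range 200 to 450 bp) and a median fold of 7.179 over the local expected read count, and 5393 of them reached at least 10-fold. Without that exclusion the count was 29388 regions covering 18.38 Mb (0.7119%), with a median width of 500 bp (350 to 800 bp), a median fold of 9.955 and 14614 regions at 10-fold or more. All 21782 regions of the first set overlapped a region of the second, called the full set from here on, and 8828 regions of the full set had no counterpart in the first. The exclusion trimmed or removed strong regions because input reads were themselves dense there, as described below, and the full set is therefore described beside the first.

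In the first set, the 12 regions with the highest fold among those with an adjusted p of at most 1e-05 were 450 to 1350 bp wide and lay on 8 chromosomes. The first was on chromosome 7 at 30978701 to 30979350, where the 200 bp summit window held 140 ChIP reads (95% Poisson interval 118 to 165) against 1.63 expected, a fold of 85.8 (72.2 to 101). The region at 125365251 to 125365850 of chromosome 8 followed with a fold of 77.7 (57.8 to 102) from 51 reads, and that at 7769601 to 7770150 of chromosome X with 74.3 (61.1 to 89.4) from 111 reads. A region on chromosome 7 at 16760501 to 16761100 had a fold of 74.0 (63.6 to 85.6) from 181 reads. The next were at 100139101 to 100139950 of chromosome 12 (fold 68.1, interval 59.3 to 77.9), at 149932351 to 149933600 of chromosome X (67.4, 59.0 to 76.7), at 20796001 to 20796550 of chromosome 14 (66.2, 52.6 to 82.3) and at 45265351 to 45266050 of chromosome X (65.8, 55.7 to 77.1). The remaining regions lay on chromosome 3 at 119890701 to 119891150 (60.9, 43.5 to 83) and at 20948201 to 20948700 (56.9, 47 to 68.3), on chromosome 13 at 48965551 to 48966900 (59.7, 50.2 to 70.6) and on chromosome 11 at 99793251 to 99793750 (58.6, 42.4 to 78.9). Their summit windows held 2 to 9 input reads, and the largest of their adjusted p-values (Poisson test per window, Benjamini-Hochberg) was 1e-53. The expected count came from the genome mean or from input over 1 kb or more, never from the 200 bp window itself. In all 12 regions, input in the summit window, scaled by 0.679, was above the expected count. Their folds are thus higher than ChIP over scaled input in the same window, and median folds have the same limit where input peaks at the summit. Chromosome X held 3 of the 12, against 5.28% of all regions of the first set. Without the exclusion, regions at 38114301 to 38115600 of chromosome 18 (fold 78.0, interval 68.9 to 88), 148629651 to 148630200 of chromosome 7 (70.4, 61.4 to 80.3) and 96325551 to 96326200 of chromosome 11 (67.8, 59.8 to 76.6) entered the first 12, and both regions of chromosome 3 and that at 99793251 of chromosome 11 left it. The intervals of neighbouring ranks overlapped, and the folds and their order also depended on scaling. With background-bin scaling the first region rose to 213, that at 16760501 of chromosome 7 to 230 and the last to 177, while the regions on chromosome 8 and at 119890701 of chromosome 3 stayed at 77.7 and 60.9. Those latter regions fell to 36.3 and 33.7 with all deposited reads and to 48.7 and 26.2 with windows of 500 bp.

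**Figure D1:**
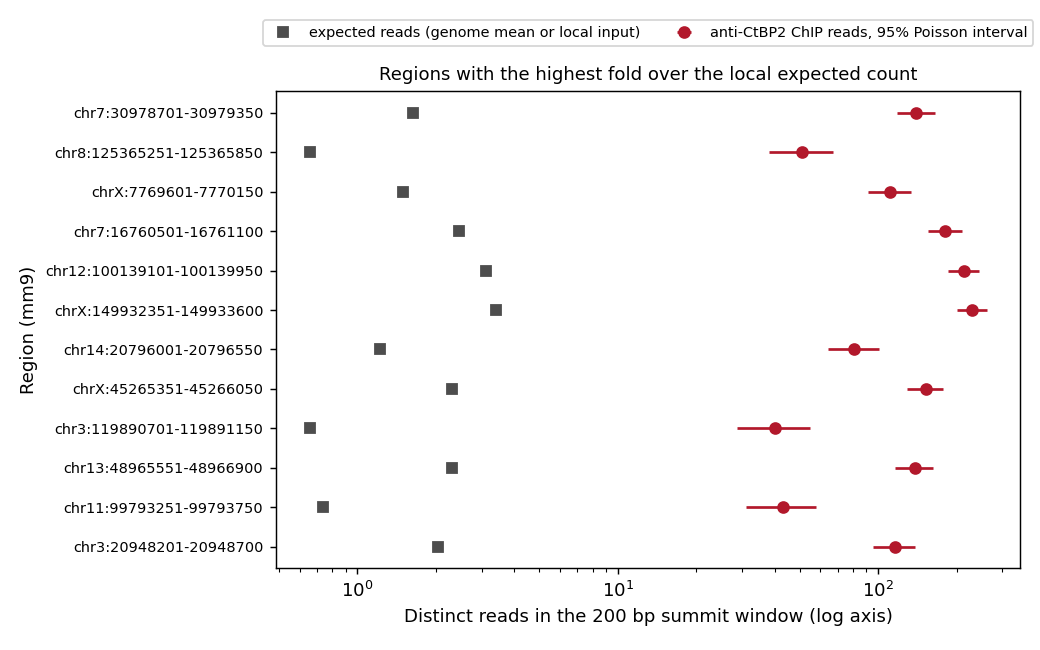
Distinct ChIP reads (red points, bars are 95% Poisson intervals) and expected reads, the largest of the genome mean and the scaled local input (grey squares), in the 200 bp summit window of the 12 regions with the highest fold in the first set, on a log axis. In each region the ChIP interval lies far above the expected count, for example 118 to 165 against 1.63 at the top.

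Regions ranked by read number were different and wider. In the full set, the region with the most reads lay on chromosome 12 at 77469901 to 77472350 and held 2356 distinct ChIP reads and 346 input reads over 2450 bp. It was followed by chromosome 8 at 11006851 to 11010050 with 2172 ChIP reads and chromosome 17 at 34255201 to 34258700 with 2161. The widest region, on chromosome 12 at 114013951 to 114023100, ran over 9150 bp with 2094 ChIP reads, and the next widest, on chromosome 8 at 53388851 to 53394150, over 5300 bp with 657. The 10% of regions with the most reads held 42.02% of all ChIP reads in regions. These rankings were chosen after the values were seen.

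The regions fell into a sparser and a denser group by ChIP read density. Among the 29364 regions of the full set outside blocks of extreme depth, log2 read density had a lower mode at 68.6 reads per kb and an upper mode at 549, with a trough at 208 where the number of regions was 0.361 of that at the smaller mode. The 10045 denser regions (34.2%) had a median width of 800 bp and medians of 491 ChIP and 96.2 input reads per kb, and they held 53.3% of all distinct ChIP reads. The 19319 sparser regions (65.8%) had a median width of 400 bp, medians of 75 ChIP and 39.3 input reads per kb, and 10.6% of the ChIP reads. Around the summit, ChIP density was 116 times that of the flanks in denser regions and 21.9 times in sparser ones. The limit at the trough was chosen after the values were seen, 1365 regions lay within 0.25 log2 units of it, and 98.7% of regions stayed in their group when all deposited reads were used.

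**Figure D2:**
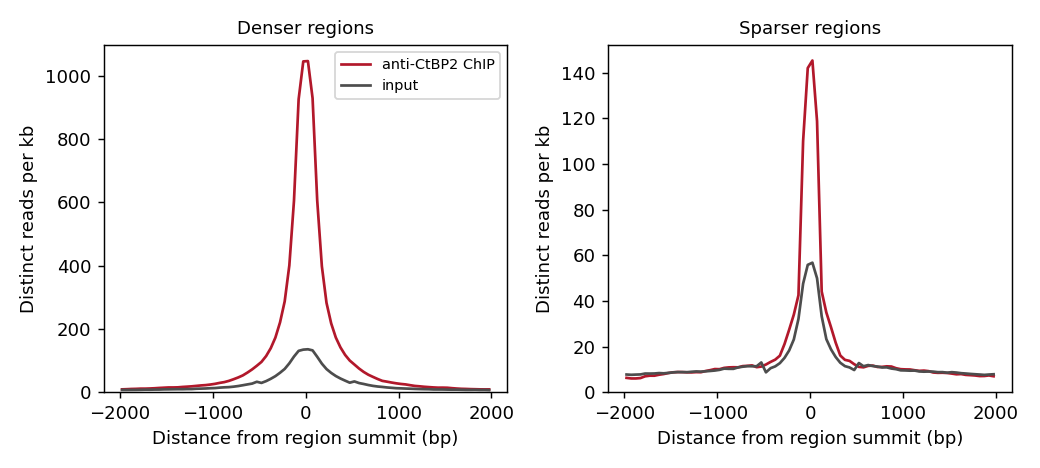
Mean distinct reads per kb against distance from the region summit in bp, for ChIP (red) and input (grey), in denser (left) and sparser (right) regions of the full set. The vertical scales differ between the panels, and both libraries peak at the summit, ChIP at 116 times and input at 19.5 times the flanks in denser regions.

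The share of reads in regions was higher in the ChIP library than in the input in each set. In the first set it was 13.27% of ChIP reads (95% Wilson interval 13.25 to 13.3) against 2.246% of input reads (2.238 to 2.254), a ratio of 5.91. In the full set it was 64.02% (63.99 to 64.06) against 10.22% (10.2 to 10.23), a ratio of 6.27. Windows of 500 bp with the exclusion gave 25.97% against 4.566%. Because these regions were called in the same reads, the ChIP reads were split at random into 2 parts of 4236624 and 4238047 reads. Regions were called in each part and the share was taken from the other part. This gave 10.83% and 10.82% in the first set and 62.08% and 62.05% in the full set. The parts gave 16639 and 16645 regions, of which 79.2% and 79.1% overlapped a region of the other part by at least 1 bp. In the full set the parts gave 25052 and 25054 regions with 89.0% and 88.9% shared. Parts of 1 library measure counting error only.

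CtBP2 regions were also places of raised input. In the first set ChIP density was 45.78 times that of the rest of the genome and input density 6.874 times, with a Spearman's rho of 0.5218 between their densities across regions. In the full set ChIP density was 248.2 times that of the rest of the genome and input density 15.87 times, and the densities of the libraries rose together across regions (Spearman's rho 0.8053, with regions not independent replicates). With regions split into 10 equal groups by ChIP density, from the sparsest to the densest group ChIP density rose from 29.9 to 577 times and input density from 3.98 to 25 times the rest of the genome. Input-enriched regions were called in the input alone against its own surroundings, with local input over 10 kb only and no high-input exclusion. With that local setting the CtBP2 call itself rose from 21782 to 32225 regions. The input-alone call gave 81175 input-enriched regions. Of the CtBP2 regions, 81.3% overlapped one of these, against 3.35% (at most 3.54%) over 20 shuffles of their positions, and the share was 99.7% in denser and 71.7% in sparser regions. In the other direction, 24262 input-enriched regions (29.9%) overlapped a CtBP2 region and 56913 (70.1%) did not. These comparisons were chosen after the values were seen.

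**Figure D3:**
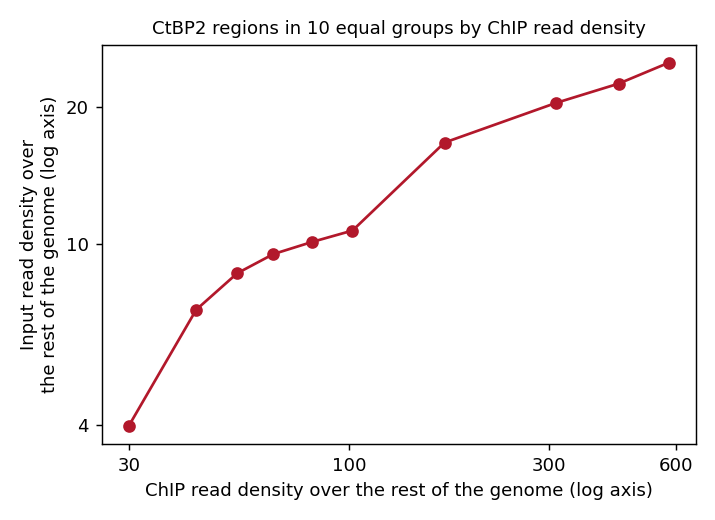
Input read density against ChIP read density for 10 equal groups of CtBP2 regions ordered by ChIP density, each relative to the rest of the genome, on log axes. ChIP density spans 29.9 to 577 times and input density 3.98 to 25 times.

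CtBP2 regions were unevenly spread along and between chromosomes. In the full set there were 11.4 regions per Mb. Among autosomes and X the number ran from 17.6 on chromosome 11 and 15.2 on chromosome 19 to 8.74 on chromosome 1 and 7.24 on chromosome X. The first set kept chromosome 11 in front at 12.1 per Mb but gave chromosome X 7.03, above autosomes 1, 3, 14 and 16. The densest 1 Mb stretches were 80 to 81 Mb and 79 to 80 Mb of chromosome 10 with 142 and 131 regions, followed by 52 to 53 Mb of chromosome 7 with 97 and 73 to 74 Mb of chromosome 8 with 94, whereas 27 of 2592 stretches of 1 Mb held no region. Neighbouring summits were a median of 39.2 kb apart, against 58.4 kb (range 57.6 to 59.1) over 100 shuffles within chromosomes, and 22.9% lay within 10 kb of the next against 11.4% in the shuffles. Denser regions made up 31.2% to 40.8% of the regions of each autosome and 16.2% (95% Wilson interval 14.2 to 18.4) of the 1176 regions of chromosome X. Read depth outside regions on chromosome X was 0.78 of the autosomal median in ChIP and 0.905 in input.

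**Figure D4:**
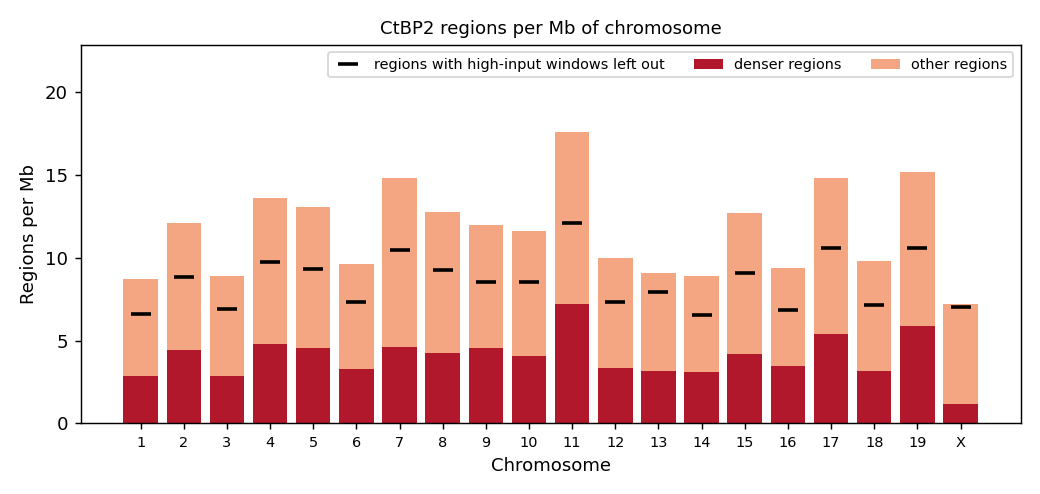
Regions per Mb for each autosome and chromosome X in the full set, as stacked bars of denser (red) and other (orange) regions, with black marks for the set that leaves out windows of high input. Chromosome 11 is highest at 17.6 per Mb and chromosome X lowest at 7.24, with the smallest denser part.

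**Figure D5:**
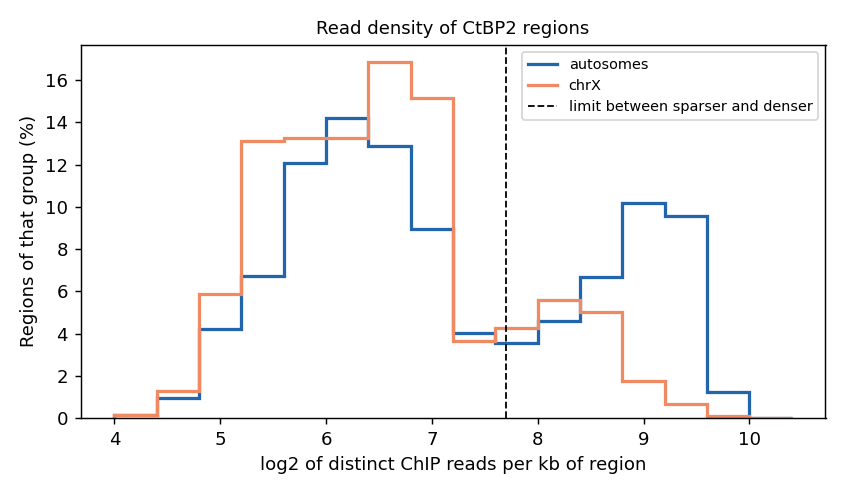
Percentage of regions against log2 of distinct ChIP reads per kb, for autosomes (blue) and chromosome X (orange) in the full set outside blocks of extreme depth, with the limit of 208 reads per kb as a dashed line. Both groups of chromosomes show a sparser and a denser mode, and 16.2% of the regions of chromosome X lie above the limit.

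Read counts of the libraries were moderately correlated along the genome. Over all 10 kb bins, log2 counts of ChIP and input reads had a Pearson correlation of 0.652 and Spearman's rho was 0.563. The values were 0.480 and 0.448 in bins without a region and 0.782 and 0.791 in bins with one. Over 1 kb bins they were 0.351 and 0.203. These correlations are across bins of 1 pair of libraries, and bins are not independent replicates.

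Exchanging the roles of the libraries gave more regions than the CtBP2 call itself. With reads scaled by library totals, the setting fixed in advance, 90026 regions were higher in input than in ChIP against 21782 higher in ChIP, and the numbers at 10-fold or more were 12796 and 5393. Scaling on background bins, where ChIP held 0.218 distinct reads per input read rather than the 0.679 of the totals, gave 14518 regions higher in input and 33001 higher in ChIP, with 2954 and 22958 at 10-fold or more. Those bins were chosen for low ChIP counts, so 0.218 is a low value. Over all sequence outside regions of the full set, ChIP held 1.189 and input 4.368 distinct reads per kb. Of the regions higher in input, 36 with the first scaling and 0 with the second overlapped a region of the full set, itself called with total-read scaling. The exchanged call left out windows with ChIP of at least 10 times its genome mean. A low overlap was thus largely set in advance. The Poisson test takes reads to be independent, so adjusted p-values near the limit overstate how rare such windows are by chance. Region counts should be read beside the exchanged counts, but these do not estimate the number of chance calls. They moved from 90026 to 14518 with the scaling, and the input held 81175 enriched regions of its own.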

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

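The tests in this part were chosen after the values were seen. The region comparisons do not describe the 24 blocks of extreme depth themselves, although 24 regions of the full set, with 0.082% of distinct ChIP reads, lay inside them. Counted with all deposited reads, 10 of the 24 blocks held a larger share of the ChIP reads than of the input reads. Against background bins, 16 blocks had more than 3 times the ChIP to input ratio, 6 of them with a smaller share in ChIP by library totals. The blocks together held 46.6% of ChIP and 34% of input reads. The block with the most reads, at 3 to 3.04 Mb of chromosome 9, held 27.4% of ChIP and 19.1% of input reads, a share ratio of 1.43. That at 98.5 to 98.51 Mb of chromosome 2 held 15.6% and 11.8%, a ratio of 1.32. The ratio was 1.44 at 35.11 to 35.12 Mb of chromosome 9, 1.43 at 3.1 to 3.12 Mb of chromosome 12 and again at 77.57 to 77.58 Mb of chromosome 13, and 1.26 at 70.03 to 70.04 Mb of chromosome 4. It was 1.22 at 75.9 to 75.91 Mb of chromosome 12, 1.1 at 3.01 to 3.02 Mb of chromosome 4 and 1.05 at 3 to 3.01 Mb of chromosome 11. The highest ratio, 4.56, was at 39.98 to 39.99 Mb of chromosome 17, where 224340 ChIP and 29401 input reads gave 28 times the ChIP to input ratio of background bins.

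The block with the most reads stood at 8.79 times the ChIP to input ratio of background bins, 0.273 with all reads. Those bins were chosen for low ChIP counts, which raises such multiples. If extreme depth or the placement of reads with many matches raised every block, none would lie below background bins, yet 8 of the 24 did. Of these, 7 had ratios of 0.183 to 0.221, not far below the 0.273 of background bins. That at 24.62 to 24.63 Mb of chromosome 1 had 0.0432, near the 0.0398 of the mitochondrial chromosome. Whether mitochondrial reads were placed there was not tested, so this block cannot speak against an effect of read placement. The other 7 speak only against an effect that raised all blocks. Blocks were picked by input depth and matches per read were not measured, so an effect on the blocks with high ratios stays open. Base composition could not be tested without the sequence of the build, and it stays open: 5 blocks, on chromosomes 2, 9, 12 and 13, had ratios within 10% of that of the block with the most reads, itself included, as blocks of like composition may have. Binding of CtBP2 to repeated sequence stays open too, and no biological explanation was tested.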

How the results depend on the processing

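No paired analysis was possible because each group had 1 library. Of 12 alternatives for the region count, 10 stayed within 1.5 times the main 21782. Background-bin scaling gave 33001, and that scaling without the high-input exclusion, added after the values were seen, gave 34908. The share of ChIP reads in regions, 13.27% in the main setting, left its counting interval in each alternative run: 12.5% with all deposited reads, 11.5% at an adjusted p of 1e-05, 13.36% with a fixed shift, and, added later, 25.97% with windows of 500 bp, 10.36% at a fold of at least 5, 16.42% with input over 10 kb only, 14.95% with thinned input, 16.47% with background-bin scaling, 64.02% without the exclusion and 66.53% with both. The 64.02% follows from the exclusion, which removes windows with dense input. The stricter adjusted p and the fold of at least 5 keep a subset of the same windows, so they could only lower the share. The causes of the other moves were not tested. The counting interval does not measure spread between settings. Spearman's rho of bin counts went from 0.563 to 0.203 with 1 kb bins. All 12 named regions were called under all 12 alternatives, with folds from 24.7 (windows of 500 bp) to 275 (input over 10 kb only). These regions were picked for the highest folds in the same reads, so that outcome was largely set in advance. The stricter adjusted p, the fold of at least 5 and the call without the exclusion could not drop them. Mapping quality limits were not run because no such values were given, nor was thinning ChIP to the input depth, since ChIP had fewer distinct reads. The promoter, gene list, neighbouring gene and motif results and their alternatives were not run. Sites of 5 times the genome mean were left undetected on simulated data. In these libraries regions below 5-fold were called, and a fold of at least 5 lowered the count to 17010.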

Other observations

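In this part, the test of read depth on chromosome X was fixed before its result was seen, and the other tests were chosen after. The mitochondrial chromosome had 0.0398 ChIP reads per input read, against 0.273 in background bins of the nuclear genome. Nuclear stretches at 24.61 to 24.63 Mb of chromosome 1, with 388 ChIP and 9754 input reads, and at 22.44 to 22.45 Mb of chromosome 2, with 82 and 2474, had ratios of 0.0398 (95% Poisson interval 0.0359 to 0.0439) and 0.0331 (0.0264 to 0.0411). On chromosome 13, read depth outside regions from 41 to 82 Mb was 0.657 (bootstrap interval over 1 Mb bins 0.624 to 0.692) of the rest of that chromosome in ChIP and 0.640 (0.586 to 0.699) in input. The 90th percentile of 10 kb bins was lower there too, at 0.722 (0.667 to 0.722) in ChIP and 0.662 (0.577 to 0.765) in input.

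Input reads were enriched at CtBP2 regions, most of all at the denser ones. If reads of the amplified ChIP library had been counted as input, input reads in regions would share their start positions with ChIP reads. The excess of shared starts over positions 30 to 90 bp away was 8.68% in input and 45.5% between 2 random parts of the deposited ChIP reads, so such reads may account for part of the input in regions but not for all of it. ChIP DNA mixed into the input, as the only source of the input excess, would make it a constant multiple of the ChIP excess. With regions in 10 equal groups by ChIP density, that multiple was 0.103 in the sparsest, 0.146 in the next and 0.0417 (0.0412 to 0.0422) in the densest, which is 0.404 and 0.286 of the sparser groups. These values speak against mixing as the only source, and mixing as a part of the input excess stays open. Preferred fragmentation or recovery of open chromatin cannot be told apart from other sources without accessibility data of the same cells, although 70.1% of input-enriched regions lay outside CtBP2 regions, and no biological explanation was tested.

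Denser CtBP2 regions were a smaller share of the regions of chromosome X than of any autosome. Their medians on chromosome X were lower than on autosomes, at 328 against 495 ChIP and 49.5 against 96.7 input reads per kb. Chromosome X held 3 of the 12 regions with the highest fold, all 3 of them denser. Fold is taken over the local expected count, so it is not a measure of ChIP density and does not go against those lower medians. Lower read depth of the whole chromosome was tested by multiplying the limit by the ChIP background ratio of 0.78, and the share on chromosome X rose to 19.9% (17.7 to 22.3), below the lowest autosome at 31.2%. More sparse calls on chromosome X would leave the number of denser regions per Mb like that of autosomes, yet it was 1.43 (1.25 to 1.62) with the scaled limit, below the lowest autosome at 2.85. A lower signal per site would move the denser mode, and that mode was lower on chromosome X. Its fullest bin was log2 8 to 8.4 with 66 regions, against log2 8.8 to 9.2 with 2863 regions on autosomes. A lower signal at denser sites may thus account for part of the smaller share. With the limit at the trough of the density histogram of chromosome X itself, near 147 reads per kb, the share was 21.1% (18.9 to 23.5), again below 31.2%. Halving the limit to 104 reads per kb gave 42% (39.2 to 44.8), above the autosomal shares at the full limit. That limit lay in the fullest bin of chromosome X, log2 6.4 to 6.8 with 198 regions, so it counted regions of the sparser mode as denser. It therefore cannot show whether a lower signal accounts for the whole difference, and no biological explanation was tested.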
